A study of Mus musculus with 9 samples.

How the data were processed

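The data were expression values of 9 Affymetrix mouse gene arrays, 1 per sample of sorted long-term haematopoietic stem cells, with 3 biological replicates in each of the groups WT, Jak2VF and Jak2VF_Ezh2KO as the labels give them. Per the labels' protocols, the mice received 5 doses of 300 µg pI-pC at 4 weeks of age, marrow was taken 12 weeks later, and stem cells were sorted by flow cytometry. RNA was extracted with RNeasy Plus Mini columns, 10 ng was amplified with the NuGEN Ovation Pico WTA V2 kit, and the product was labelled with biotin, per the labels' protocols. The submitters' processing notes name Partek 6.6.

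The deposited table holds log2 values of 41345 probe sets, already processed by the authors, and the values themselves show this scale, with array medians between 5.51 and 5.68. The background correction, normalization and summary behind these values are not given in the sources used here. No further normalization was applied. The 3 arrays per group limit the precision of every difference.

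Probe sets were named from the platform annotation, in which 23521 had 1 gene symbol, 1814 had several and 16010 were unnamed here. Those with several symbols or none were not used to name a gene. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over the 9 arrays was kept, which left 22180 genes. The reference gene table (GRCm38.p6) served only for symbols and for the order of neighbouring genes, since the build of the array is not given in the sources used here. All probe sets outside the named ones were tested separately.

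The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with all 9 arrays in 1 fit and 3 contrasts. The fit had 6 residual degrees of freedom, a prior of 3.83 degrees of freedom and a prior standard deviation of 0.206. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Fold changes are powers of 2 of the log2 difference, standard errors are those of the moderated fit, and adjusted p-values of single genes come from limma.

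Gene lists were tested with camera, in both directions, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. Of 25 lists, 24 had the 5 measured members needed, and the sex-linked list, with 4 measured, was not tested. The lists hold 776 unique genes, of which 692 were measured and 37 lie only on probe sets with several symbols. They cover megakaryocyte and platelet, erythroid, neutrophil granule, monocyte and macrophage, B cell, T and NK cell, mast cell and basophil, and stroma and endothelial genes. They further cover stem cell genes, progenitor genes kept out by the gate, Polycomb subunits and related genes, Hox genes, fetal stem cell genes, developmental transcription factors, CDK inhibitors with p53 targets and senescence genes, and STAT targets. The last ones hold type I interferon, interferon-gamma, NF-kB, cell cycle, TGF-beta, immediate early, ribosomal protein and oxidative phosphorylation genes.

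Groups, tests, lists, the main alternatives and the rule for named genes were fixed before the data were examined. Per contrast the rule names, among genes that passed with no overlap between groups, the 10 with the largest change each way, filled up by the smallest unadjusted p where fewer passed. It adds up to 4 members of each list with the smallest p, and always Ezh2, Ezh1 and Jak2. Predicted genes, RIKEN clones, small RNA genes and olfactory and vomeronasal receptors were counted and not named. Further list members that passed over their list alone, and genes named in the closing tests, were chosen after their values were seen.

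Alternatives were an intensity trend with robust variance, ordinary least squares without moderation, quantile normalization, median centring, leaving out the dimmer part of the genes, the 2 groups of a contrast alone, array weights, every probe set tested, the replicate number as a block, a sex covariate, each array left out in turn, and other thresholds. For lists, an estimated correlation and fry were added. Chosen after seeing the data were leaving out both arrays with Y-linked signal, the sex covariate in the list test, and a covariate for the mean receptor-gene signal of each array.

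The fit was tested on simulated data for Jak2VF against WT over 22180 genes. It recovered 81% of 100 genes changed by 1 log2 unit and 98% of 100 changed by 2 units, and 11 of 190 calls were among unchanged genes. The adjusted threshold is stricter where fewer genes change than the 200 changed here. These shares therefore do not show how many changes of this size were missed in the real comparisons. A list shifted by 0.5 in Jak2VF_Ezh2KO was called, and 0 unshifted lists were called. The simulated genes varied independently of each other, whereas the real lists had estimated correlations of up to 0.777. The simulation therefore does not show how often unshifted lists are called in the real data.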

Results

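Gene expression was measured in long-term haematopoietic stem cells sorted from the bone marrow of C57BL/6 mice as lineage-negative, Sca-1-positive, c-kit-positive cells without CD34 and CD135. The 9 arrays fell into 3 groups of 3 biological replicates, namely wild-type controls (WT), mice with 1 mutant Jak2 allele switched on by MxCre (Jak2VF), and mice with the same Jak2 allele and deletion of Ezh2 (Jak2VF_Ezh2KO). All mice had received pI-pC, which activates MxCre, 12 weeks before harvest. Array medians lay between 5.51 and 5.68 on the log2 scale, and pairwise correlations across probe sets lay between 0.898 and 0.968. Of the 3 Jak2VF_Ezh2KO arrays, replicates 1 and 2 carried Y-linked signal and low Xist, whereas replicate 3 and the 6 arrays of the other groups had the signal of female mice.

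**Figure D1:**
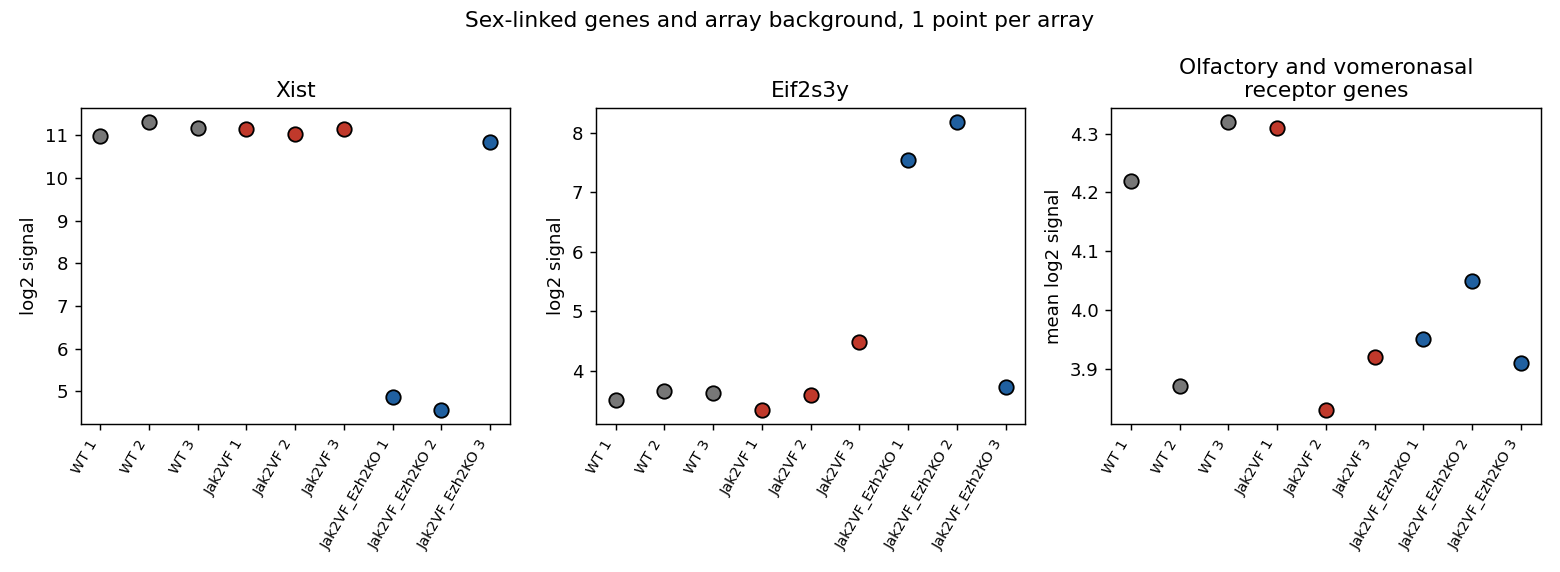
Log2 signal of Xist and of the Y-linked gene Eif2s3y, and mean log2 signal of 1390 olfactory and vomeronasal receptor genes (y axes), with 1 point per array (x axis). Xist was 4.86 and 4.56 in Jak2VF_Ezh2KO replicates 1 and 2, and the receptor mean was 4.22 to 4.32 in WT replicates 1 and 3 and Jak2VF replicate 1.

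Ezh2, the catalytic subunit of Polycomb repressive complex 2, gave a signal of 8.66 ± 0.17 in WT, 8.91 ± 0.16 in Jak2VF and 8.32 ± 0.21 in Jak2VF_Ezh2KO (log2, SD, n = 3). The single arrays read 8.48, 8.81 and 8.69 in WT, 8.87, 9.09 and 8.78 in Jak2VF, and 8.47, 8.08 and 8.42 in Jak2VF_Ezh2KO. The difference between Jak2VF_Ezh2KO and Jak2VF was -0.59 with a standard error of 0.16, with all 3 knockout arrays below all 3 Jak2VF arrays, but it did not pass over all genes (limma, adjusted p = 0.411). Against WT it was -0.34 (adjusted p = 0.596). Where the Ezh2 probe set lies relative to the deleted part of the gene is not given in the sources used here, so a retained signal does not test the deletion. Ezh1, the alternative catalytic subunit, differed by 0.12 between Jak2VF_Ezh2KO and Jak2VF (adjusted p = 0.918). Jak2 differed by 0.25 between Jak2VF and WT (adjusted p = 0.924) and by -0.46 between Jak2VF_Ezh2KO and Jak2VF (adjusted p = 0.539), and its level does not test the mutant allele.

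**Figure D2:**
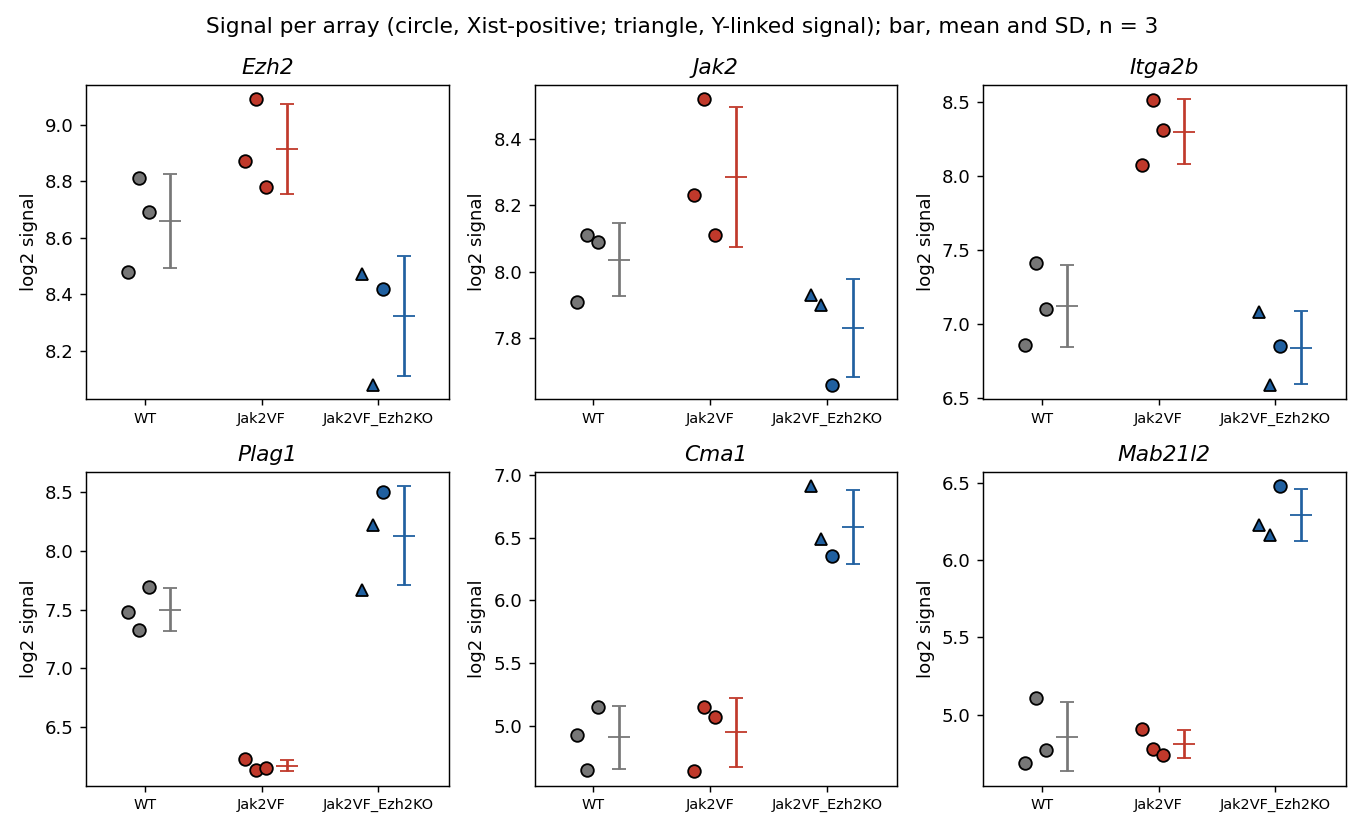
Log2 signal of Ezh2, Jak2, Itga2b, Plag1, Cma1 and Mab21l2 on each of the 9 arrays (y axis, log2 signal; x axis, group), with the mean and SD of 3 arrays beside the points and triangles for the arrays with Y-linked signal. Itga2b averaged 8.29 in Jak2VF against 7.12 in WT and 6.84 in Jak2VF_Ezh2KO.

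The comparison of Jak2VF with WT addressed the effect of the mutant Jak2 allele. The labels name MxCre in the mutant groups, and whether the control mice carried it is not given in the sources used here, so comparisons with WT may also include the Cre transgene. The list with the smallest p held genes of the interferon-gamma response, which lay higher in Jak2VF as a list of 25 measured genes with a mean of 0.45 (camera adjusted p = 1.57e-09, but adjusted p = 0.255 with an estimated correlation). Of these, 13 were higher and 1 lower when adjusted over the list alone, and 0 passed over all genes. Examples were the major histocompatibility complex class II gene H2-Eb1, at 5.99 ± 0.18 in WT and 6.99 ± 0.26 in Jak2VF (SD), H2-Ab1, 1.38 higher, the interferon-induced GTPase Igtp, 1.14 higher, and Nlrc5, an activator of class I genes, 0.70 higher (adjusted p = 0.308, 0.924, 0.308 and 0.696 over all genes). Megakaryocyte and platelet genes lay higher with a mean of 0.29 over 24 genes (adjusted p = 0.000598, but adjusted p = 0.453 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. The list mean relative to WT was 0.403 and 0.383 in Jak2VF replicates 2 and 3 but 0.072 in replicate 1, next to 0.066 in WT replicate 2. Among the members, the integrin subunit gene Itga2b was 1.17 ± 0.19 (SE) higher, or 2.25-fold, Gp5 was 1.01 higher and Mmrn1 differed by -0.73.

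Stem cell genes lay lower in Jak2VF, with a mean of -0.15 over 37 genes (adjusted p = 0.000222, but adjusted p = 0.453 with an estimated correlation), 4 of them lower and 1 higher when adjusted over the list alone. Sult1a1 differed by -1.28, the transcription factor gene Mecom by -0.71 and Procr, which encodes the endothelial protein C receptor, by -0.64. The list mean relative to WT was -0.275 in Jak2VF replicate 1, -0.134 in replicate 2 and -0.025 in replicate 3, which lay within the WT arrays, and without replicate 1 the mean difference was -0.08. Mast cell and basophil genes lay higher, with a mean of 0.49 over 14 genes (adjusted p = 0.000222, but adjusted p = 0.255 with an estimated correlation), and 5 were higher when adjusted over the list alone, including Fcer1a at 1.62 and Cpa3 at 1.44. The list named progenitor genes kept out by the gate lay higher with a mean of 0.36 over 16 genes (adjusted p = 0.000464, but adjusted p = 0.453 with an estimated correlation). Of these, 4 were higher when adjusted over the list alone, such as Cd48 at 1.20. WT replicate 2, at 0.412, lay above Jak2VF replicates 1 and 3, at 0.223 and 0.39. The mean difference was 0.57 without WT replicate 2 and 0.23 without WT replicate 3. CD48 was not a sort marker, and Cd34, the gene of a marker that was, read 9.91 to 10.68 over all arrays. These RNA values therefore do not show whether cells outside the gate were present. STAT target genes, with Pim1 at 0.88 and Socs3 at 0.29, lay higher over 27 genes (mean 0.20, adjusted p = 0.000464, but adjusted p = 0.453 with an estimated correlation), with 0 members passing over the list alone. The other probe sets of Pim1 and Socs3 differed by 0.31 and 0.49. Of the STAT targets, 20 had a positive and 7 a negative difference, with Cish at -0.28 (-0.08 in its other probe set). The STAT list mean relative to WT was 0.052 in Jak2VF replicate 1, below the 0.112 of WT replicate 2. Type I interferon response genes lay higher by a mean of 0.19 (adjusted p = 0.00402, but adjusted p = 0.453 with an estimated correlation), also with 0 members passing over the list alone.

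Cell cycle genes lay higher by a mean of 0.28 over 47 genes, 44 of them with a positive difference (adjusted p = 1.52e-06, but adjusted p = 0.665 with an estimated correlation). This rested on single arrays, since the list mean relative to the WT average was 0.69 in Jak2VF replicate 2 and -0.37 in WT replicate 1. The adjusted p became 0.576 without the former and 0.185 without the latter, with mean differences of 0.07 and 0.09. The mean was 0.44 without WT replicate 2 and 0.42 without Jak2VF replicate 3. Fetal stem cell genes lay lower by a mean of -0.13 (adjusted p = 0.0213, but adjusted p = 0.475 with an estimated correlation), with adjusted p = 0.322 without Jak2VF replicate 2 and 0.16 without WT replicate 1. Their mean was then -0.04 and -0.08, and it was -0.20 without WT replicate 2 and -0.21 without Jak2VF replicate 3. Monocyte and macrophage genes lay higher by a mean of 0.26 (adjusted p = 0.038, but adjusted p = 0.629 with an estimated correlation). This call was lost without any 1 of WT replicates 2 and 3, Jak2VF replicates 1 and 3 or Jak2VF_Ezh2KO replicate 2, where adjusted p was 0.13, 0.194, 0.0569, 0.435 and 0.0505. The mean fell to 0.16 without WT replicate 3 and to 0.15 without Jak2VF replicate 3. It was also lost with quantile normalization, with the dimmer part of the genes left out and, as chosen after seeing the data, without both arrays with Y-linked signal.

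Single genes did not pass. Over 22180 genes, 0 differed between Jak2VF and WT with limma at the adjusted threshold of 0.05. The smallest adjusted p was 0.308, and 0 passed with ordinary least squares without moderation. At an unadjusted p under 0.05, 632 genes were higher and 402 lower, where 1109 were expected by chance in all, and groups did not overlap for 6.11% of genes, where chance gives 10%. Besides those already named, the genes with the smallest p were Rec8, Lrrc66, Insl6, Rnf19b, Gpc3 and Mfsd13a on the higher side, from 0.59 for Lrrc66 to 1.31 for Insl6. On the lower side were Plag1 at -1.33, Bex1 at -0.99, Emcn at -1.40, Cyp2c38 at -1.09, Plac8l1 at -0.92, Rps15a-ps2 at -0.95, Tspan6 at -0.89 and Mllt3 at -0.56. The mean signal of olfactory and vomeronasal receptor genes, which these cells are not known to use, was 4.22 and 4.32 in WT replicates 1 and 3 and 4.31 in Jak2VF replicate 1, against 3.83 to 4.05 in the other 6 arrays.

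The comparison of Jak2VF_Ezh2KO with Jak2VF addressed the loss of Ezh2 in the presence of the mutant Jak2 allele. In all, 10 genes passed, 7 higher and 3 lower. Plag1, a zinc-finger transcription factor gene, rose by 1.96 with a standard error of 0.20, or 3.88-fold (limma, adjusted p = 0.0159), from 6.17 ± 0.05 in Jak2VF to 8.13 ± 0.42 in Jak2VF_Ezh2KO, with WT at 7.50 ± 0.18 (SD, n = 3). Mab21l2, a developmental gene, rose 2.79-fold from 4.81 ± 0.09 to 6.29 ± 0.16 (SD, n = 3), with adjusted p = 0.0159. The mast cell protease gene Cma1 rose 3.09-fold, Lst1 3.03-fold and Chchd7 1.89-fold (each with adjusted p = 0.0441). Itga2b fell by 1.45 with a standard error of 0.19, or 2.74-fold (adjusted p = 0.0441), from 8.29 ± 0.22 to 6.84 ± 0.25 (SD, n = 3), and each of these genes had all 3 arrays of one group beyond all 3 of the other. The remaining 4 were 2 RIKEN-clone genes that fell and a predicted gene and a vomeronasal receptor gene that rose. The receptor gene is of a class that these cells are not known to use. Cma1, Mab21l2 and the receptor gene belong to the dimmer part of the genes, and with this part left out 7 of the 10 calls were kept.

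Megakaryocyte and platelet genes lay lower in Jak2VF_Ezh2KO, with a mean of -0.38 over 24 genes (adjusted p = 1.23e-05, but adjusted p = 0.353 with an estimated correlation), and 5 were lower when adjusted over the list alone. Besides Itga2b these were Plek at -1.39, Gp5 at -1.26, Itgb3 at -0.82 and Fli1 at -0.59. Erythroid genes lay higher by a mean of 0.49 over 27 genes, 25 of them with a positive difference (adjusted p = 9.09e-11, but adjusted p = 0.353 with an estimated correlation), and 4 were higher when adjusted over the list alone. These were the metallothionein gene Mt2 at 2.22, the blood group gene Rhd at 1.26, Blvrb at 1.15 and Tspan33 at 1.05. The erythroid list mean varied within groups, at 0.43 in Jak2VF replicate 2 against -0.30 in Jak2VF replicate 1 relative to WT. Jak2VF_Ezh2KO replicate 3, at 0.411, lay below Jak2VF replicate 2. The mean difference was 0.34 without Jak2VF replicate 1 and 0.70 without Jak2VF replicate 2. Type I interferon response genes lay higher by a mean of 0.25 over 34 genes (adjusted p = 7.5e-08, but adjusted p = 0.216 with an estimated correlation), with 29 positive differences and Ifit1 at 0.82 as the 1 member higher when adjusted over the list alone.

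Stem cell genes lay higher by a mean of 0.13 (adjusted p = 0.0023, but adjusted p = 0.602 with an estimated correlation), with 3 members higher when adjusted over the list alone, namely Sult1a1 at 1.25, Gprasp2 at 1.10 (0.60 in its other probe set) and Procr at 0.90. T and NK cell genes lay higher by a mean of 0.40 over 17 genes (adjusted p = 0.000558, but adjusted p = 0.216 with an estimated correlation). When adjusted over the list alone, 4 of them were higher and 2 lower, with the interleukin-7 receptor gene Il7r at 1.95, the chemokine gene Ccl5 at 1.77, Klrd1 at 1.69, Gzmb at 0.84, Nkg7 at -0.75 and Thy1 at -0.50. Mast cell and basophil genes lay higher by a mean of 0.29 (adjusted p = 0.0188, but adjusted p = 0.353 with an estimated correlation), with 4 higher, among them the proteases Cma1 and Mcpt4, and 1 lower when adjusted over the list alone. This call was lost without Jak2VF replicate 3 or Jak2VF_Ezh2KO replicates 1 or 3, and both lineage calls were lost with the dimmer part of the genes left out. The stem cell call was lost without Jak2VF replicate 1 or Jak2VF_Ezh2KO replicate 3, where the mean was 0.06 and 0.08. Its sign was opposite to that of Jak2VF against WT, but both comparisons share the Jak2VF arrays, which alone can give this. An exact permutation of the stem cell list mean, Jak2VF against all other arrays, gave p = 0.381 when adjusted over the lists.

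Cell cycle genes lay lower by a mean of -0.21 (adjusted p = 0.0023, but adjusted p = 0.89 with an estimated correlation), and without Jak2VF replicate 2 the direction of the test turned, with a mean of -0.01 and adjusted p = 0.699. The mean was -0.36 without Jak2VF replicate 3. B cell genes lay higher by a mean of 0.26 (adjusted p = 0.0158, but adjusted p = 0.763 with an estimated correlation). Their list mean was 0.82 in Jak2VF_Ezh2KO replicate 3 against -0.16 and -0.01 in replicates 1 and 2, and adjusted p was 0.969 without replicate 3, 0.203 without Jak2VF replicate 2 and 0.0559 without Jak2VF replicate 3. Their mean difference was -0.04 without Jak2VF_Ezh2KO replicate 3 and 0.45 without replicate 1. Immediate early and heat shock genes, a sign of handling, lay higher by a mean of 0.22 (adjusted p = 0.0188, but adjusted p = 0.763 with an estimated correlation), with 0.79 in Jak2VF_Ezh2KO replicate 3, without which the call was lost, as it was without Jak2VF replicates 1 or 3. Their mean difference was 0.02 without Jak2VF_Ezh2KO replicate 3, 0.34 without Jak2VF_Ezh2KO replicate 1 and 0.13 without Jak2VF replicate 1. Oxidative phosphorylation genes lay higher by 0.11 (adjusted p = 0.0023, but adjusted p = 0.763 with an estimated correlation). Ribosomal protein genes did so by 0.08 (adjusted p = 0.00435, but adjusted p = 0.744 with an estimated correlation). Hox genes did so by 0.07 (adjusted p = 0.0334, but adjusted p = 0.763 with an estimated correlation). The ribosomal and Hox calls were lost without Jak2VF_Ezh2KO replicate 3, and the oxidative phosphorylation and ribosomal calls without Jak2VF replicate 3. The Hox call was also lost without Jak2VF replicates 1 or 2 or Jak2VF_Ezh2KO replicate 2, with the dimmer part of the genes left out and, in settings chosen after seeing the data, without both arrays with Y-linked signal and with sex as a covariate. The receptor-gene covariate, also chosen after seeing the data, ended the immediate early call. With Jak2VF replicates 1, 2 or 3 left out in turn, the mean was 0.06, 0.23 and 0.04 for oxidative phosphorylation, 0.05, 0.13 and 0.05 for ribosomal protein and 0.02, 0.03 and 0.16 for Hox genes. Without Jak2VF_Ezh2KO replicate 3 it was 0.04 for ribosomal protein genes, and without replicates 1 or 2 it was 0.11 and 0.04 for Hox genes.

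Further genes named by the rule fixed in advance did not pass. On the higher side these were Fam169a at 0.85, Cd7 at 1.87, Ebi3 at 1.38 (0.76 in its other probe set), Klrd1 at 1.69 and the transcriptional regulator gene Id2 at 1.64, with adjusted p from 0.0542 to 0.0934. On the lower side were Gpc3, H2ac15, Rap1b, Hmgn5, Plek, Stmn1, Mapkapk2, Hnrnpdl and S1pr3, from -2.07 for the histone gene H2ac15 to -0.67 for Stmn1. At an unadjusted p under 0.05, 645 genes were higher and 884 lower, and groups did not overlap for 11.1% of genes, where chance gives 10%. The count of 10 became 0 without any 1 of the Jak2VF replicates or without Jak2VF_Ezh2KO replicate 2, 1 without replicate 1, 17 without replicate 3 and 4 to 5 without a WT array. Without replicate 3 both remaining knockout arrays are male, and 9 of the 17 genes were on the Y chromosome or Xist, with 6 shared with the 10. It also became 0 with ordinary least squares without moderation, with the 2 groups alone, with every probe set tested, and, as chosen after seeing the data, without both arrays with Y-linked signal. With sex as a covariate 7 genes passed, of which Plag1 was the 1 shared with the 10. Over the alternatives the log2 changes lay between 1.77 and 2.33 for Plag1, 1.39 and 1.66 for Mab21l2 and 1.39 and 1.74 for Cma1. They lay between 1.46 and 1.88 for Lst1, 0.85 and 1.05 for Chchd7, and -1.57 and -1.33 for Itga2b. Many alternatives, such as those without moderation or without a WT array, cannot move a difference of these 2 group means. The ranges are therefore no separate support for the calls.

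**Figure D3:**
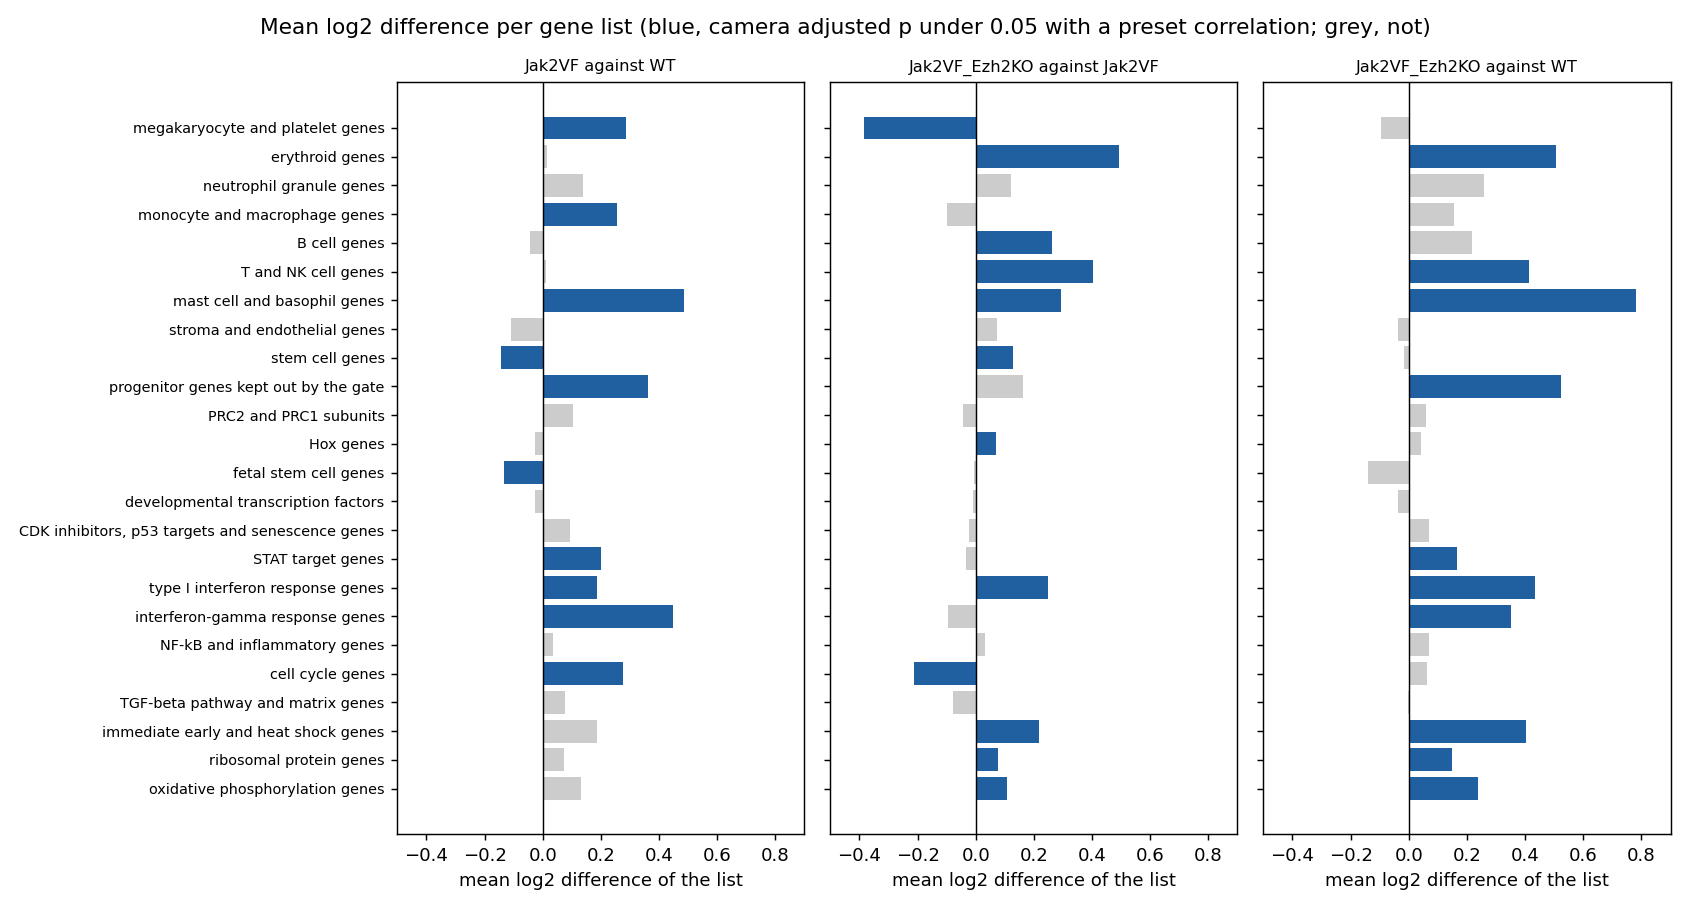
Mean log2 difference of each gene list tested (x axis, log2; 1 bar per list) in the 3 comparisons, blue where the camera adjusted p with a preset correlation was under 0.05 and grey otherwise. Megakaryocyte and platelet genes averaged 0.29 for Jak2VF against WT and -0.38 for Jak2VF_Ezh2KO against Jak2VF, and no list passed with an estimated correlation.

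The comparison of Jak2VF_Ezh2KO with WT addressed both genetic changes together. Here 5 genes passed, 4 higher and 1 lower. Cma1 rose 3.19-fold (limma, adjusted p = 0.0459), Mab21l2 rose 2.70-fold (adjusted p = 0.0304) and Fam169a rose 2.06-fold, from 4.88 ± 0.09 to 5.92 ± 0.08 (SD, n = 3), with adjusted p = 0.0363. The others were a vomeronasal receptor gene that rose and an olfactory receptor gene that fell. Both belong to the receptor classes that these cells are not known to use, so these calls are not read as stem cell changes. Cma1, Mab21l2 and Fam169a were dim, at 4.65 to 5.15 in WT against array medians of 5.51 to 5.68. Like the vomeronasal receptor gene, they belong to the dimmer part of the genes. With this part left out, 1 of the 5 calls was kept. Type I interferon response genes lay higher by a mean of 0.44 over 34 genes (adjusted p = 3.97e-13, but adjusted p = 0.0636 with an estimated correlation), and 10 were higher when adjusted over the list alone, including Oas1g at 1.26, Oas2 at 1.06, Isg15 at 1.02 and Zbp1 at 0.99. Mast cell and basophil genes lay higher by 0.78 (adjusted p = 8.28e-08, but adjusted p = 0.0636 with an estimated correlation), 7 of 14 when adjusted over the list alone, with the basophil protease gene Mcpt8 at 2.24 and Cpa3 at 1.77. Both lists also passed fry, which tests a list without comparing it with other genes (adjusted p = 0.0185 and 0.0129).

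Erythroid genes lay higher by a mean of 0.51, 26 of 27 with a positive difference (adjusted p = 6.7e-09, but adjusted p = 0.39 with an estimated correlation), with Mt2 at 2.20 as the 1 member passing over the list alone. Interferon-gamma response genes lay higher by 0.35 (adjusted p = 1.33e-06, but adjusted p = 0.296 with an estimated correlation), 5 higher and 1 lower when adjusted over the list alone. The progenitor list lay higher by 0.53 (adjusted p = 0.000142, but adjusted p = 0.39 with an estimated correlation). In it, 4 members were higher when adjusted over the list alone, among them the lymphoid gene Dntt at 2.08. T and NK cell genes lay higher by 0.41 (adjusted p = 0.00102, but adjusted p = 0.149 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone. Oxidative phosphorylation genes lay higher by 0.24 (adjusted p = 3.04e-06, but adjusted p = 0.554 with an estimated correlation). Immediate early and heat shock genes lay higher by 0.40 (adjusted p = 8.43e-05, but adjusted p = 0.39 with an estimated correlation). Jak2VF_Ezh2KO replicate 3, at 0.788 against 0.16 and 0.263 in replicates 1 and 2, carried much of this, and without it the mean difference was 0.21. STAT targets lay higher by 0.17 (adjusted p = 0.00318, but adjusted p = 0.435 with an estimated correlation). Their list mean relative to WT was 0.105 in Jak2VF_Ezh2KO replicate 1, below the 0.112 of WT replicate 2. Ribosomal protein genes lay higher by 0.15 (adjusted p = 0.005, but adjusted p = 0.554 with an estimated correlation). The STAT and ribosomal calls were lost without WT replicate 3, and the ribosomal call also without Jak2VF_Ezh2KO replicate 3. Leaving out the dimmer part of the genes ended the T and NK, STAT and ribosomal calls, and the receptor-gene covariate, chosen after seeing the data, ended the STAT and ribosomal calls.

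Genes that did not pass included, on the higher side, Cd7 at 2.18, Nenf, Phf11d, Mcpt8, Mpped2, Cenpv and Il18r1, with adjusted p from 0.0716 to 0.106. On the lower side were Cyp2d40, H2ac15 at -2.04, Cdr1 at -1.66, Nlrp9c, Cyp2c38, Hmgn5, Psma8, Slc36a4, Rab10 and Eldr, with adjusted p from 0.081 to 0.27. The probe set used for Slc36a4 differed by -0.74, whereas the other probe set of this gene differed by 0.49. At an unadjusted p under 0.05, 1008 genes were higher and 900 lower, and groups did not overlap for 12.9% of genes, where chance gives 10%. The count of 5 became 0 without WT replicate 1, Jak2VF replicates 2 or 3 or Jak2VF_Ezh2KO replicates 1 or 2, 1 without WT replicate 3, 2 without WT replicate 2 and 14 without Jak2VF_Ezh2KO replicate 3, of which 9 were on the Y chromosome or Xist and 3 were shared with the 5. It was 0 with ordinary least squares without moderation, with the 2 groups alone, with every probe set tested and, in settings chosen after seeing the data, without both arrays with Y-linked signal or with the receptor-gene signal of each array as a covariate. With sex as a covariate 6 genes passed, 0 of them among the 5. Over the alternatives the log2 change of Cma1 lay between 1.44 and 1.80 and that of Mab21l2 between 1.34 and 1.62. Here too, many alternatives cannot move the difference of the group means, so these ranges are no separate support.

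Polycomb subunits and related genes, a list that also held demethylase genes such as Kdm6a that remove the Polycomb mark, had 28 measured members and passed in none of the 3 comparisons, with camera adjusted p of 0.0732 for Jak2VF against WT, 0.974 for Jak2VF_Ezh2KO against Jak2VF and 0.201 for Jak2VF_Ezh2KO against WT. Developmental transcription factors that are classical Polycomb targets likewise passed in none (81 genes, adjusted p = 0.132, 0.659 and 0.468). The same held for CDK inhibitors, p53 targets and senescence genes (adjusted p = 0.224, 0.806 and 0.196), NF-kB and inflammatory genes (0.838, 0.586 and 0.671), TGF-beta pathway and matrix genes (0.157, 0.366 and 0.788), neutrophil granule genes (0.157, 0.797 and 0.107) and stroma and endothelial genes (0.157, 0.46 and 0.729). For Jak2VF_Ezh2KO against Jak2VF the median and the mean differed in sign for neutrophil granule genes (-0.07 and 0.12) and NF-kB genes (-0.01 and 0.03). They also did so for the progenitor list (-0.07 and 0.16) and the Polycomb list (0.01 and -0.05). In that comparison the test direction was higher although median and mean were negative for developmental transcription factors (mean -0.01), CDK inhibitors, p53 targets and senescence genes (mean -0.02), monocyte and macrophage genes (mean -0.10) and fetal stem cell genes (mean -0.01). For Jak2VF against WT the test direction was lower although the mean was positive for erythroid genes (median -0.06, mean 0.02), T and NK cell genes (-0.09 and 0.01) and NF-kB genes (0.00 and 0.04). For Jak2VF_Ezh2KO against WT it was higher with a negative median for NF-kB genes (-0.01, mean 0.07) and TGF-beta pathway and matrix genes (-0.03, with a mean just under 0).

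Both comparisons that involve the knockout shared 3 called genes, Cma1, Mab21l2 and the vomeronasal receptor gene, all higher. Independent lists would share 0.00126 higher genes, a value that leaves out the shared arrays. Simulated unchanged groups with the same shared arrays gave a mean of 0, a value that leaves out any effects. Neither is what sharing arrays alone would give here, and with 3 arrays per group the knockout arrays could not be split, so part of the overlap may come from them. Over all genes the covariance of the log2 differences was 0.0517, against 0.0225 in the simulation, a difference of 0.0292. For Jak2VF against WT and Jak2VF_Ezh2KO against Jak2VF it was -0.0202 against -0.0226, a difference of 0.0024, with 0 shared genes. For Jak2VF against WT and Jak2VF_Ezh2KO against WT it was 0.038 against 0.0224, a difference of 0.0155, again with 0 shared genes.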

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

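The tests of sex and of array background were chosen after the result was seen, and so was the receptor-gene covariate. The counts of other splits were set beforehand.

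Signal outside the comparisons marked the sex of the mice. The Y-linked gene Eif2s3y read 7.54 in Jak2VF_Ezh2KO replicate 1 and 8.18 in replicate 2, above the 3.34 to 4.48 of the other 7 arrays. Xist, which is transcribed from the inactive X chromosome, read 4.86 and 4.56 in the same arrays, below the 10.84 to 11.31 elsewhere. In this series 2 of the 3 Jak2VF_Ezh2KO samples therefore differ from all WT and Jak2VF samples in sex as well as genotype.

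The 10 genes called between Jak2VF_Ezh2KO and Jak2VF were weighed against sex and array background. The receptor-gene signal of the knockout arrays, 3.91 to 4.05, lay within the 3.83 to 4.31 of the Jak2VF arrays, so an effect of background in 1 direction would place the knockout values between the Jak2VF values. All 10 genes had the 3 knockout arrays beyond the 3 Jak2VF arrays, but genes called in this comparison are largely separated by their selection. Their separation therefore does not test array background, and the values show only that the receptor-gene ranges overlap. A covariate for this signal says little here, since the group means were alike (3.97 and 4.02) and it moved the log2 changes by a median of 0.02 over all genes. In WT the receptor-gene signal was 4.22, 3.87 and 4.32, against the 3.91 to 4.05 of the knockout arrays. The covariate also takes up a residual degree of freedom by construction. Against WT this covariate ended all 5 calls, although the log2 changes barely moved. That of Cma1 went from 1.67 ± 0.20 (SE) to 1.66 ± 0.23 and its adjusted p rose to 0.133. The cause was not tested.

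Sex stays open. Among 13 genes called from the 2 male arrays alone, 69.2% had the female knockout array beyond all 3 Jak2VF arrays in the same direction, 8 of the 8 not on the Y chromosome and 1 of the 5 on it. Any excess counted, as for Trgv5, with 0.21 in the female array and 1.73 in the males. In the others not on the Y chromosome the female change was 0.65 to 1.32 times the male one. The same Jak2VF arrays served in calling these genes, which favours this outcome. The median ratio of the female to the male change was 0.784 over the 8 genes, and 0.654 with those on the Y chromosome, whose signal sex fixes. In all 10 genes called from the 3 knockout arrays, the female array lay beyond all 3 Jak2VF arrays, although it had a part in choosing these genes. With sex as a covariate their log2 changes were 0.815 to 1.192 times those without it, and 1 of the 10, Plag1, was still called, at 2.33 ± 0.24 (SE). Both male arrays are in the knockout group, so these changes are those of the female array alone against Jak2VF and add no separate evidence. Losing the other calls therefore speaks neither for nor against sex. What separates sex from genotype rests on 1 female knockout array, which keeps sex open beside the Ezh2 genotype.

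Other splits of the 6 arrays of each comparison into 3 and 3 number 10, too few for a share under 0.05. For Jak2VF_Ezh2KO against Jak2VF the real split called 10 genes and the highest other split 0, so 1 of 10 splits called as many. For Jak2VF_Ezh2KO against WT these were 5 and 1, again 1 of 10. For Jak2VF against WT the real split called 0 genes, so all 10 called as many, and the highest called 144. That split set WT replicates 1 and 3 and Jak2VF replicate 1 against WT replicate 2 and Jak2VF replicates 2 and 3, and the first 3 are those with the higher receptor-gene signal. A split that calls this many genes points to a structure of the samples other than genotype. With the receptor-gene covariate, 0 genes passed for the real split. Of the lists, the real splits called 10, 12 and 10 in the order Jak2VF against WT, Jak2VF_Ezh2KO against Jak2VF and Jak2VF_Ezh2KO against WT, the highest other splits called 9, 11 and 12, and 1, 1 and 4 of the 10 splits called as many.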

How the results depend on the processing

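The settings without both arrays with Y-linked signal, with the array background covariate and with sex in the list test were chosen after seeing the data. A reversal was counted only where a value passed in the main or the alternative setting, so other changes of sign count as kept. Of the planned values, 7312 kept their side of the threshold with no reversal so counted, 79 newly passed, 213 no longer passed and 2 reversed. Of the added ones these were 879, 17, 18 and 0. The cause was not tested except where fewer arrays or more tests enter by construction. For Jak2VF against WT, 0 genes passed in each setting except unadjusted p with 1.5-fold, which gave 344. For Jak2VF_Ezh2KO against Jak2VF (10 genes) the count was 0 without moderation, with the 2 groups only, with every probe set and without both arrays with Y-linked signal, 4 with median centring, 19 without the dim genes, 23 at adjusted p under 0.1 and 535 at unadjusted p with 1.5-fold. Leaving out 1 array gave 0 to 17. The sex covariate gave 7 genes, 1 of them among the 10. For Jak2VF_Ezh2KO against WT (5 genes) the count was 0 without moderation, with the 2 groups only, with every probe set, without both arrays with Y-linked signal and with the array background covariate. It was 10 with the intensity trend, 3 with median centring, 14 with array weights, 13 at adjusted p under 0.1 and 770 at unadjusted p with 1.5-fold, and 0 to 14 with 1 array left out. The sex covariate gave 6 genes, 0 of them among the 5. With the replicate number as a replicate block, 0 genes passed in each comparison, while list counts stayed within 1.5 times. Same-numbered arrays correlated at -0.231 to 0.484 in their deviations, 2 of 9 pairs above 0.1, and 0 arrays correlated best with their own number in both other groups, although WT replicate 2 and Jak2VF replicate 2 correlated best with each other (0.484), and WT replicate 1 correlated best with Jak2VF replicate 1 (0.207), which correlated best with WT replicate 3 (0.333). The arrays are thus taken to share only a number. With an estimated correlation 0 lists passed in each comparison, and with fry 0, 0 and 2 (the last for Jak2VF_Ezh2KO against WT). Lists called for Jak2VF_Ezh2KO against Jak2VF (12) ranged from 6 to 12 with 1 array left out. Genes shared by both knockout comparisons went from 3 to 7 at adjusted p under 0.1. The cell cycle list reversed for Jak2VF_Ezh2KO against Jak2VF without Jak2VF replicate 2 (adjusted p = 0.699; 3.04e-09 to 0.699 over the arrays left out). It also reversed for Jak2VF_Ezh2KO against WT without WT replicate 1 (adjusted p = 0.038; 0.0011 to 0.807). The low signal of dim genes limits what can be read from them.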

Other observations

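The tests in this part were chosen after the result was seen, and the genes they name outside the rule were picked after their values were seen.

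The neutrophil granule list was not called for Jak2VF_Ezh2KO against Jak2VF (camera adjusted p = 0.797). Of its members with the smallest p, the calcium-binding protein genes S100a8 and S100a9 differed by 2.85 ± 0.83 (SE) and 1.61 ± 0.44, while the granule genes Ctsg and Ms4a3 differed by -1.32 and -0.89, none of them past the threshold over all genes (adjusted p = 0.474, 0.416, 0.606 and 0.539). S100a8 read 7.75, 6.74 and 9.91 in the 3 knockout arrays, highest in replicate 3. Emcn, an endothelial mucin gene also found on stem cells, differed by -1.40 between Jak2VF and WT and by 1.10 between Jak2VF_Ezh2KO and Jak2VF (adjusted p = 0.589 and 0.335). In the Polycomb list, the subunit genes Bmi1 and Cbx7 differed by 0.71 and 0.53 and the X-linked demethylase gene Kdm6a, which is not a subunit, by -0.59 between Jak2VF_Ezh2KO and WT (adjusted p = 0.438, 0.411 and 0.466). The male knockout arrays carried most of this for Bmi1, with 6.94 and 6.81 against 6.16 in the female one and 5.87 to 6.02 in WT. The same held for Kdm6a, with 7.55 and 7.26 against 8.02 in the female one and 8.10 to 8.32 in WT. Probe sets with several symbols or none, 17824 in all, gave 0 calls with limma in each comparison, with 655, 1195 and 1648 at an unadjusted p under 0.05.

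Megakaryocyte and platelet genes lay higher in Jak2VF than in both other groups. The list mean relative to WT was 0.403 and 0.383 in Jak2VF replicates 2 and 3. In Jak2VF replicate 1 it was 0.072, barely above the 0.066 of WT replicate 2, the highest of the other 6 arrays. The difference between the 3 and the 6 arrays was 0.33, and the exact permutation p of 0.0119 (2-sided) is the smallest that the 84 splits can give. Adjusted over the lists it was 0.286. So few splits leave array differences not tied to genotype open, and these cannot be told apart from genotype. Platelets or megakaryocytes among the sorted cells may contribute, and only Ppbp was usable for a test, with a change of 0.15, against the 0.585 that 0.5 of the Itga2b change would give. As this rests on 1 gene, the explanation stays open. The cells were sorted as lineage-negative, and whether this removed platelets and megakaryocytes was not tested. A stem-cell programme of these genes is a biological candidate explanation that was not tested apart from these.

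In Jak2VF_Ezh2KO against Jak2VF, the mast cell protease gene Cma1 passed, and the NK cell gene Klrd1 lay higher without passing. The 2 lists that hold them lay higher, but neither call held with an estimated correlation (camera adjusted p = 0.353 and 0.216). As a rule, mast cells or basophils among the sorted cells were taken to raise the 13 other genes of their list against Jak2VF. The bound was 0.5 of the Cma1 change, which is 0.813. Their median was 0.17, with 7 higher and 6 lower, and lay below that bound by more than the SD of 0.556 between them. The rule cannot decide, since an admixture would move the log2 value of a dim gene more than that of a bright one. Cma1 read only 4.64 to 5.15 in Jak2VF. Against WT, 12 of the 14 list members were positive, with a median of 0.67. Mast cells or basophils as the source therefore stay open. The abundant mast cell gene Cpa3 averaged 8.54 in Jak2VF and 8.87 in Jak2VF_Ezh2KO. For NK or T cells the median of the 16 other genes was 0.23, with 11 higher and 5 lower, against a bound of 0.847 and an SD of 0.727 between them, so NK or T cells may contribute. Ccl5 averaged 7.90 in Jak2VF and 9.67 in Jak2VF_Ezh2KO, whereas Nkg7 averaged 9.86 and 9.11. Sex of the mice and the Ezh2 genotype stay open as well. A narrower choice of 8 mast cell and 9 T and NK cell genes, tried first, gave medians of -0.10 and 0.16, but it had left out genes that rose and was set aside for that reason. The cells were sorted as lineage-negative, and whether this removed mature cells of either kind was not tested.

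Plag1 and Chchd7, which both rose in Jak2VF_Ezh2KO against Jak2VF, are neighbours in the gene order of the reference. Among the 23 genes at adjusted p under 0.1, 1 adjacent pair was found, against a mean of 0.0201 in 10000 random sets. This pair had prompted the test, so its presence does not count in favour of an explanation, and it was the sole pair. Shared local regulation or a shared chromosomal segment may account for it and stays open. For Jak2VF_Ezh2KO against WT, 13 genes held 0 pairs.

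Insl6, next to Jak2 in the gene order, was 1.31 and 1.57 higher than WT in Jak2VF and Jak2VF_Ezh2KO. An effect of the modified Jak2 locus on its neighbours may be involved, but the median absolute change of the 10 genes around Jak2 was 0.21, at percentile 87.8 of random windows, with a median of 0.133 and a 95th percentile of 0.246 among them. This neither excludes nor shows such an effect, and an effect on Insl6 alone was not tested.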
